A study of Caenorhabditis elegans with 2 samples.

How the data were processed

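Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of eGFP-tagged MAB-5 was made from whole Caenorhabditis elegans embryos of mixed stage. The labels name the strain OP27, which carries the unc-119(ed3) mutation and the integrated transgene wgIs27. They give 2 biological replicates, which form 1 group, so the design has no comparison between groups. The size range given for both libraries was 150 to 350 bp. The antibody field of the labels names mab-5, while the description says that the precipitation was against the eGFP fusion.

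The authors deposited 4 peak lists for each of the genome builds ce11 and ce10. Per the file descriptions, peaks were called on each replicate with a control alignment and on both replicates pooled, as relaxed lists that include background. A thresholded list was then derived from these 3 by the irreproducible discovery rate (IDR). The peak caller, the aligner, their versions and the extraction protocol are not given in the sources used here. The control library is not analysed here. Each relaxed list held 30000 peaks, and the thresholded list held 502 in ce11 and 478 in ce10.

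The deposited signal value of each peak is the authors' own enrichment measure, whose scale is not given in the sources used here. It was used to describe and rank peaks within a list. The deposited −log10 of the q-value was 1.86 for each of the 502 thresholded ce11 peaks and was not used to rank them. The thresholded list equalled the 502 peaks of the pooled list with the highest signal value. Read depth is unknown, so no value has a counting error from reads, and intervals over peaks or genes are exact 95% binomial intervals that cover counting error only.

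Analyses used the ce11 lists with the WBcel235 genome and the gene models of Ensembl release 115. The last peak of the pooled ce11 list on X ended at position 17718942, the length of X in WBcel235, and no ce11 peak passed the end of a chromosome. Gene symbols came from the RefSeq table of the same assembly, matched by locus, because Ensembl gives several loci one name. They were found for 99.9% of 19973 nuclear protein-coding genes. No coordinates were converted between builds, and the ce10 lists were used in their own coordinates, with shares of chromosome length taken from WBcel235. The 21 mitochondrial peaks of the thresholded list were left out of all analyses of position, genes and motifs, which used the 481 nuclear peaks.

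A gene start window ran from 2000 bp upstream to 500 bp downstream of the start of a protein-coding gene, and a gene with a summit in its window is called a target. The share of summits in these windows was tested, one-sided, against 1000 rotations of the summits along their chromosomes and set beside 10000 random positions. The shares on X, in the central 50% of the autosomes and in each annotated feature were tested with two-sided exact binomial tests. Gene lists were tested with the two-sided Fisher's exact test against all nuclear protein-coding genes. Of 29 lists, 28 had at least 3 members and were tested, with Benjamini-Hochberg adjustment over them. Motifs, 8 in number, were searched on both strands within 100 bp of each summit and compared with a flank centred 500 bp away by the exact McNemar test, with Benjamini-Hochberg adjustment. Medians and correlations were tested with 100000 permutations, two-sided. Density around mab-5 was the count of relaxed peaks from 20000 bp before to 20000 bp after the gene, as a percentile of windows of that size placed every 10000 bp on the autosomes.

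The groups, gene lists, motifs, tests, thresholds (adjusted p below 0.05) and most alternatives were fixed before the data were examined. So was the rule for named genes, which took the gene start nearest to each of the 15 strongest peaks and 14 genes chosen in advance. It also took up to 4 members of each list past the threshold and up to 2 of each other list, by signal value. The 15 strongest nuclear peaks were added after the values were seen, because 11 of the 15 strongest peaks were mitochondrial. Alternatives were the 251 listed peaks with the highest signal values, the strongest peaks of 1 replicate's own list, other gene windows, other flanks, windows matched within 2 percentage points of GC content, and the ce10 lists.

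The statistics were tested on simulated data with the real genome and its 19973 genes. Among 20 sets of 481 random positions, 2 gave a promoter p below 0.05, with fewer rotations than in the main test, and 0 gene lists and 0 motifs were called. Random positions were not drawn to differ from their flanks in GC content, as the real summits did (41.7% against 35.8%). The simulation therefore does not check the motif test against base composition. In a set with 15 planted members of 1 list and 120 planted sites of TGATNNAT, the planted list and motif were both called. No other list was called, but 1 other motif was, TAATKR. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.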

Results

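MAB-5 is an Antennapedia-type Hox transcription factor that patterns the posterior body of C. elegans. Its binding in mixed-stage embryos was mapped by ChIP-seq of an eGFP fusion in 2 biological replicates of 1 group. The purpose of the experiment, as far as the labels give it, was to locate the fusion protein along the genome. The thresholded list held 502 peaks, of which 481 lay on nuclear chromosomes and 21 on the mitochondrial genome. Signal values, the authors' own measure of enrichment, ran from 34.3 to 408 in this list, with a median of 43. Chromosome III carried 99 peaks, or 7.18 per Mb, and chromosome I 102, or 6.77 per Mb. Chromosomes II, IV, V and X carried 66, 74, 64 and 76 peaks. The number of reads per sample is unknown.

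The strongest nuclear sites were the mab-5 and egl-5 genes themselves in both replicates, while the lower ranks of the replicates differed. The site upstream of mab-5 ranked 2 of 30000 in the relaxed list of replicate 1 and 7 of 30000 in that of replicate 2, and the egl-5 site ranked 5 and 3. Of the 502 listed peaks, 65.1% ± 13.5 (SD, n = 2) had their summit inside one of the 502 strongest peaks of a replicate's own list, with 55.6% in replicate 1 and 74.7% in replicate 2. Both replicates covered 204 of the peaks in this way, and 52 were covered by neither. These counts include the mitochondrial peaks. The listed peaks were selected from the 2 replicates pooled, so neither this recovery nor the correlations below are independent checks. Across the 492 listed peaks found in both relaxed lists, the replicates' signal values had a Spearman correlation of 0.307 and a Pearson correlation of 0.753. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. Peaks are not independent replicates, and without the mitochondrial peaks, an alternative chosen after seeing the data, the correlations were 0.247 and 0.658. Signal values of replicate 2 were higher than those of replicate 1, with a median ratio of 1.91, and the 2 scales were not compared further.

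The region from mab-5 to egl-5 on chromosome III, which holds both posterior Hox genes of this cluster, contained 6 of the 15 strongest nuclear sites of the thresholded list. The strongest nuclear peak (III, 7784177 to 7784491, ce11) had its summit 879 bp upstream of the start of mab-5, in intergenic sequence, with a signal value of 236. Within mab-5, 2 further summits at 7780817 and 7778716 lay in introns, with signal values of 118 and 109. The second of these was closer to the start of the neighbouring gene bath-15. Over egl-5, an Abdominal-B-type Hox gene, 1 interval from 7814344 to 7816971 carried 4 summits. They had signal values of 150 and 126 in introns, 91.8 in a coding exon and 225 in the 3′ UTR, the last 2223 bp downstream of the gene start. All 4 lay beyond 500 bp downstream of the start, so egl-5 was not counted as a target. From 50 kb left of mab-5 to 50 kb right of egl-5 there were 11 listed summits, 2.29% of the nuclear ones.

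**Figure D1:**
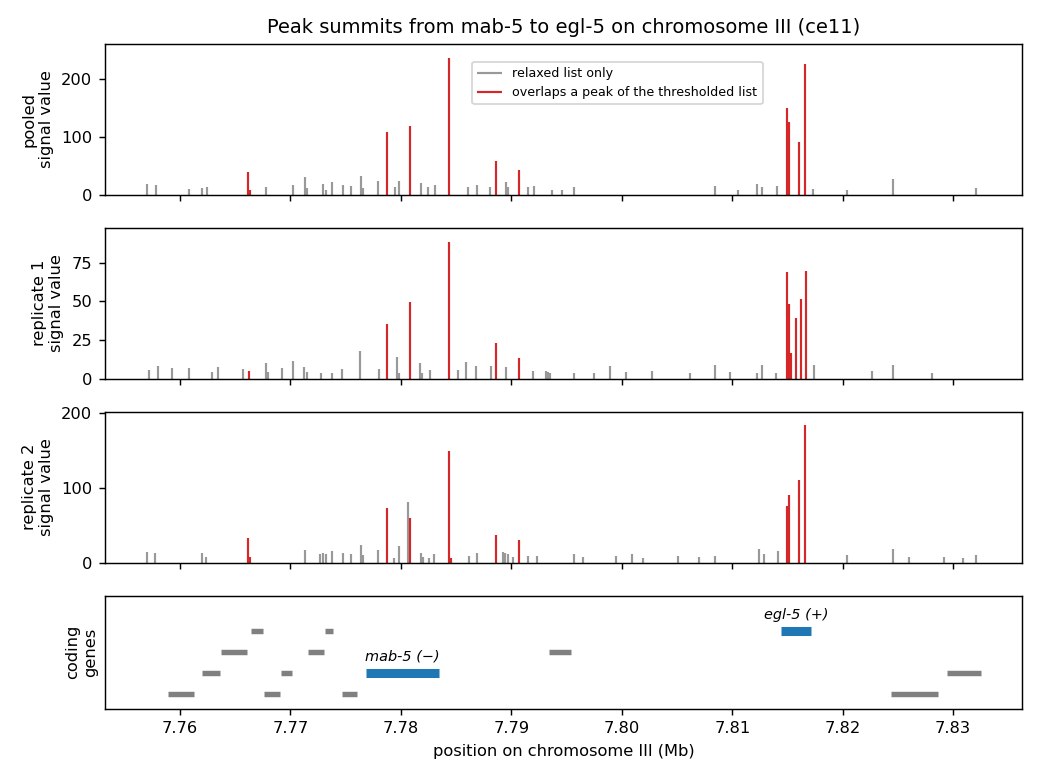
Peak summits around mab-5 and egl-5, with position on chromosome III in Mb on the horizontal axis and the authors' signal value on the vertical axes, which differ in scale between the pooled list and the 2 replicates. Each line is a summit, red where its peak overlaps the thresholded list and grey otherwise, above bars for protein-coding genes (mab-5 and egl-5 in blue), and the tallest pooled lines stand at 236 upstream of mab-5 and at 225 in egl-5.

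Weaker peaks were also dense around mab-5. From 20000 bp before to 20000 bp after the gene, the relaxed lists held 43 peaks in replicate 1, 42 in replicate 2 and 39 in the pooled list, against a median of 14 in autosomal windows of that size. These counts lay at percentiles of 99.99, 99.98 and 99.98 among 8234 windows. Around unc-119, whose rescue marks transgenic animals in this strain type, the same window held 25 peaks in replicate 1 (percentile 98.3) and 15 in replicate 2 (percentile 59.7). With 50 kb on each side of unc-119, the percentiles were 98.2 and 94.5. The start window of unc-119 held 0 peaks of the pooled relaxed list.

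Among the other Hox genes, ceh-13, the labial-type gene, had a listed peak (III, 7554707 to 7555046) with a summit 783 bp upstream of its start and a signal value of 94.0. It ranked 22 and 77 in the lists of replicates 1 and 2. The nearest listed summit to lin-39, the Sex combs reduced-type gene, lay at -7751 bp from its start with a signal value of 48.5, outside its window. The Abdominal-B-type genes php-3 and nob-1 had 0 listed summits within 10000 bp of their starts. With mab-5 and ceh-13, 2 of 6 Hox genes were targets (33.3%, exact 95% interval 4.33 to 77.7%), against 2.48% of all genes (Fisher's exact test, adjusted p = 0.0348). The call rests on 2 genes. In the exact test it was lost with windows reaching 5000 bp upstream (adjusted p = 0.0725) and without the mab-5 to egl-5 region (0.279, chosen after seeing the data), and in the permutation test with target flags rotated along the order of genes (adjusted p = 0.174). Over all 9 alternatives, the adjusted p ran from 0.00158 to 0.279.

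The Hox cofactor genes held no target, and 2 genes linked to mab-5 in earlier genetics were targets. The Meis-type cofactor gene unc-62 had a strong summit at -5530 bp from its start (V, 4491761 to 4492100, signal value 74), outside its window. The only listed summit within 10000 bp of the PBX-type gene ceh-20 lay at -7772 bp, by the start of eef-1A.1. None of 5 cofactor genes was a target, and a count of 0 of 5 allows a share of up to 52.2%. Of 13 genes linked to mab-5 in earlier genetics, lin-17 and cwn-1 were targets (15.4% against 2.48% of all genes, adjusted p = 0.102, Fisher's exact test). Both are also members of the Wnt list below. Among the 251 listed peaks with the highest signal values the list passed the threshold (Fisher's exact test, adjusted p = 0.0315, in a range from 0.0315 to 0.512 over 9 alternatives). Within 10000 bp of the starts of hlh-8, egl-20, mig-13 and egl-1 there were 0 listed summits.

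Genes of the Wnt pathway, which acts with mab-5 in neuroblast migration, were targets more often than other genes. They made up 5 of 31 (16.13%, exact 95% interval 5.45 to 33.7%, Fisher's exact test, adjusted p = 0.00516). lin-17, a Frizzled receptor gene, had a summit 553 bp upstream (I, 2706160 to 2706499) with a signal value of 74.5. cwn-1, a Wnt ligand gene, had one 448 bp upstream (II, 133876 to 134215) with a signal value of 67.8. mig-5, a Dishevelled gene, and mom-1, a Porcupine gene, had summits 192 and 752 bp upstream with signal values of 54 and 43.7. The remaining target, hmp-2, had one 1400 bp upstream with a signal value of 42.4. The mig-5 summit also lay in the start window of the chaperonin gene cct-1, and the hmp-2 summit in that of K05C4.7. Likewise, the cwn-1 summit lay in the start window of K10B4.1, and the mom-1 summit in that of lev-9. The hmp-2 and mom-1 summits were nearer to the starts of K05C4.7 and lev-9. The cwn-1 peak ranked 47 in replicate 2 and 1568 in replicate 1. With the strongest peaks of replicate 1 alone in place of the thresholded list, the Wnt list had 9.68% targets and an adjusted p of 0.138. Its adjusted p ran from 0.00149 to 0.138 over 9 alternatives.

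Ribosomal protein genes stood out among the gene lists. Of 75 such genes, 21 were targets (28%, exact 95% interval 18.2 to 39.6%, Fisher's exact test, adjusted p = 2.21e-15), where 1.86 would follow from the overall share. Their summits lay 35 to 452 bp upstream of the gene start. The strongest was 270 bp upstream of rps-20 (I, 14469264 to 14469433, signal value 106), between rps-20 and the divergent gene ekl-4. rpl-18A, rpl-15 and rpl-3 had signal values of 77.2, 73.2 and 72.9. Translation factor genes were targets in 6 of 39 cases (15.4%, Fisher's exact test, adjusted p = 0.00259), with eef-1A.1, eif-3.C, eif-3.B and eif-6 at signal values of 57.2, 53.8, 50.3 and 40. The eif-6 summit lay 1994 bp upstream and was also in the start window of tba-2. Without replicate 2 the translation factors had an adjusted p of 0.159, within a range of 0.00251 to 0.159.

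Cell cycle genes were also over-represented, with 6 of 36 among the targets (16.7%, exact 95% interval 6.37 to 32.8%, Fisher's exact test, adjusted p = 0.0022). pcn-1, the gene for the replication clamp PCNA, had a signal value of 58.7 and a summit 302 bp upstream. The E2F gene efl-1 and the retinoblastoma gene lin-35 had signal values of 44.2 and 43.3, and cdk-4 one of 37.1. The lin-35, cdk-4 and cyb-1 summits also lay in the start windows of vps-51, F18H3.1 and orc-5, whose starts were nearer. The efl-1 summit also lay in that of fbxa-90 but was nearer to efl-1, and the cki-2 summit lay 1993 bp upstream. The cdk-4 peak ranked 460 in replicate 2 and 15740 in replicate 1. Heat shock and stress genes had 4 targets of 33 (12.12%, exact test, adjusted p = 0.0348), namely hsp-110, hsp-60, hsp-1 and hsp-12.1, at signal values of 94.6, 76.1, 52.5 and 35.6. The hsp-110 summit also lay in the start window of the proteasome gene rpn-3. Without replicate 2 the cell cycle list had an adjusted p of 0.452 (range 0.00213 to 0.452 over 9 alternatives). The heat shock call was lost with rotated flags (0.149), with the 5000 bp window (0.121) and with the nearest gene start alone (0.298), in a range from 0.0074 to 0.298.

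Chemoreceptor genes, a list taken by gene symbol (sr with further letters, str or odr, then a number), were targets less often than other genes. The symbol alone does not show that each member encodes a receptor of sensory neurons. Only 8 of 1373 had a summit in their window (0.583%, exact 95% interval 0.252 to 1.14%, Fisher's exact test, adjusted p = 9.76e-07), where 34.1 would follow from the overall share. srbc-58, srh-24, srd-43 and srh-2 had the highest signal values among them, at 59.0, 47.8, 46.4 and 45.6. The srbc-58 summit also lay in the start window of sti-1, and the srh-2 summit in that of icl-1. The srh-24 summit also lay in the start windows of algn-13 and R10D12.13. In each of these cases the other gene start was nearer to the summit. Nuclear hormone receptor genes had 1 target of 269, nhr-280 (Fisher's exact test, adjusted p = 0.0573), and C-type lectin genes 1 of 239, clec-53 (adjusted p = 0.0943). F-box genes had 3 of 322, with fbxb-58 and fbxc-44 the strongest (exact test, adjusted p = 0.161).

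Lists of differentiated tissues held few or no targets. None of 34 body wall muscle, 19 pharyngeal, 38 intestinal, 28 pan-neuronal and 34 epidermal structural genes was a target. The same held for 47 neuronal identity regulators, 20 mesoderm and M lineage regulators and 23 Notch pathway genes. The upper 95% bounds of these shares ran from 7.55% for neuronal identity regulators to 17.6% for pharyngeal genes, so that a share at the overall level was not excluded (adjusted p = 1 for each, Fisher's exact test). The guidance gene plx-2, the RUNX gene rnt-1 and the maternal RNA-binding gene spn-4 were the only targets in the guidance, epidermal regulator and germline lists. Cell death genes had 3 targets of 27, with ced-2 and pig-1 the strongest (exact test, adjusted p = 0.0891). Homeobox genes named ceh had 4 of 64, led by ceh-13 and ceh-38 (exact test, adjusted p = 0.161), and histone genes 4 of 72, led by the divergent pair his-67 and his-68 (adjusted p = 0.208). Collagen genes had 3 of 156, led by col-94 and col-71, and neuropeptide genes 2 of 147, ins-39 and nlp-76 (exact test, adjusted p = 1 for both). With the strongest peaks of 1 replicate in place of the thresholded list, the muscle, pan-neuronal, M lineage and germline lists could rise above the overall share and the epidermal regulators fall to 0, without passing the threshold.

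**Figure D2:**
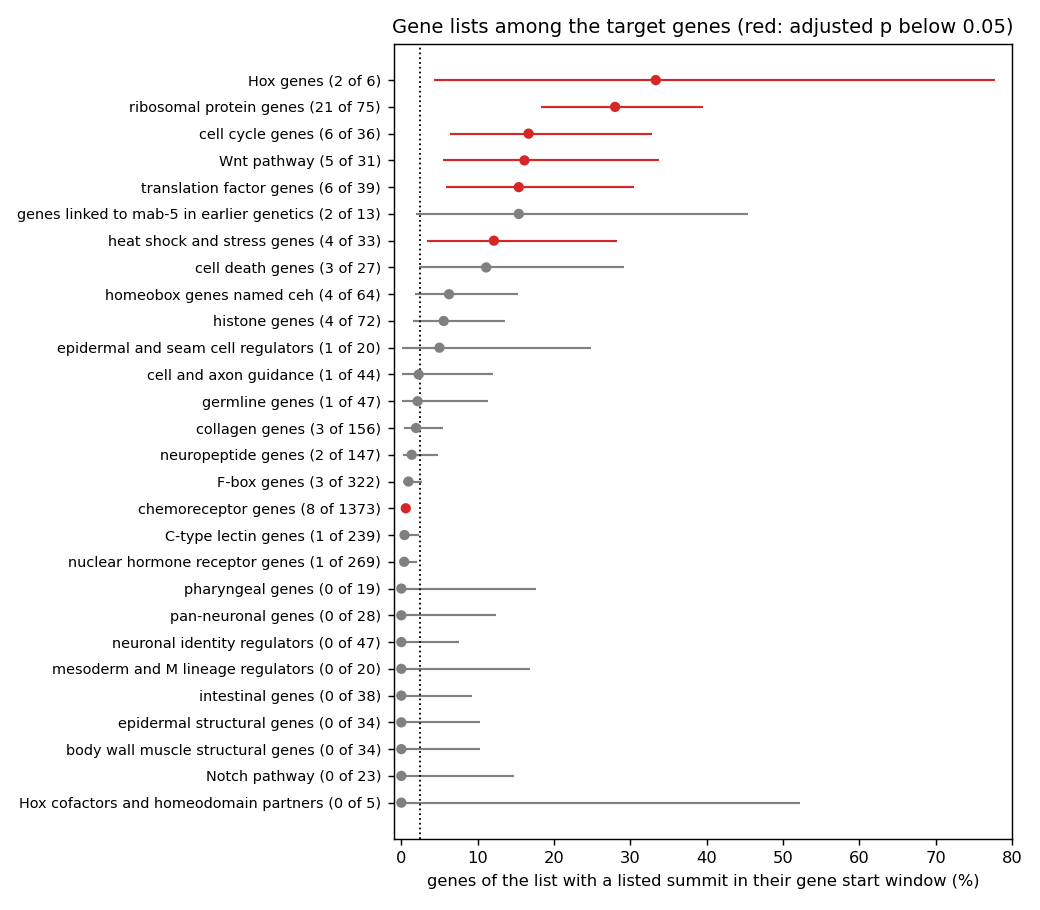
Share of genes with a listed summit in their start window, in percent, for the 28 gene lists tested, with exact 95% binomial intervals as lines and the share of all genes (2.48%) as a dotted line. Red marks lists with an adjusted p below the threshold, of which 6 lie above the dotted line and the chemoreceptor genes, at 0.583%, below it.

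Summits concentrated at gene starts and outside coding sequence. Of 481 nuclear summits, 305 (63.4%) lay in a gene start window, against 39.2% ± 2.22 (SD over 1000 rotations) and 40.2% of 10000 random positions. No rotation exceeded 45.7%, and the one-sided permutation p was 0.001, the smallest that 1000 rotations can give. These windows belonged to 496 target genes. Intergenic sequence held 351 summits (73% against 37.3% of bases), introns 21.6% against 33.3% and coding exons 3 (0.624% against 24.6%). The 5′ UTRs held 15 summits (3.12% against 1.43% of bases) and the 3′ UTRs 8 (1.66% against 3.32%). Each of the 5 features differed from its share of bases (two-sided exact binomial tests, adjusted p from 6.67e-56 to 0.0407).

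On X, fewer summits lay at gene starts than on the autosomes. There, 36 of 76 X summits (47.4%) and 269 of 405 autosomal summits (66.4%) lay in a start window (two-sided Fisher's exact test, p = 0.00264, chosen after seeing the data), while the windows cover 33.9% of X and 41.2% of the autosomes. X held 15.8% of nuclear peaks (exact 95% interval 12.7 to 19.4%), against 17.7% of bases (exact binomial p = 0.309). The strongest peaks of replicate 1 alone put the share at 18.6%, above that of bases (exact binomial p = 0.592). On the autosomes, the central 50% of the chromosomes held 227 of 405 peaks (56.0%, exact 95% interval 51.1 to 60.9%, exact binomial p = 0.017). Among the 251 listed peaks with the highest signal values that share was 56.4% with an exact binomial p of 0.0854. The binomial test counts summits as independent, while the 11 listed summits around mab-5 and egl-5 all lie in the central part of chromosome III. The central share was not run without them.

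Promoter and distal peaks did not differ detectably in strength. The median signal value was 41.9 in 305 peaks at gene starts and 43.9 in 176 other peaks (two-sided permutation test, p = 0.104). With replicate 1's own signal values the medians were 14.7 and 16.6 (p = 0.0177, permutation test), and with those of replicate 2 they were 29.4 and 29.7 (p = 0.662, permutation test). The strongest distal nuclear peaks outside the Hox region were on X. They included one at -4900 bp from the start of xol-1, the switch gene of sex determination (X, 8036303 to 8036480, signal value 123). Among promoter peaks, those upstream of lido-8 (II, 2995070 to 2995278, signal value 164) and of thum-1 (V, 2672748 to 2672918, signal value 123, in an intron of kel-8) were the strongest after mab-5.

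The composite site of Hox proteins with PBC cofactors (TGATNNAT) was more frequent at summits than beside them, and more so away from gene starts. It occurred in 138 of 481 summit windows (28.7%) and in 77 flanks (16%, exact McNemar test, adjusted p = 1.86e-05). Examples with it were the summits upstream of ceh-13, lin-17 and unc-62 and one in mab-5. Single summits were not tested, and 16% of flanks held it too. In a split by location, chosen after the shares over all summits had been seen, it passed the threshold at the 176 summits outside gene start windows (40.3% against 17.05% of flanks, exact McNemar test, adjusted p = 1.22e-05). At the 305 inside it did not (22% against 14.4%, exact McNemar test, adjusted p = 0.066). The simple homeodomain site TAATKR showed no such difference, at 34.7% of summits and 37.2% of flanks (exact test, adjusted p = 0.566). Against GC-matched windows, of which 26.4% held TAATKR, the direction turned and the adjusted p was 0.0104, in a range from 0.0104 to 1 over 8 alternatives. The direction also turned with the strongest peaks of replicate 2 alone (37.1% against 34.2%, exact test, adjusted p = 0.569). On X alone, TGATNNAT occurred at 27.6% of 76 summits and 28.9% of flanks (exact test, adjusted p = 1, chosen after seeing the data).

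The largest difference was in GAGA repeats. GAGAGA occurred in 193 summit windows (40.1%) and 47 flanks (9.77%, exact McNemar test, adjusted p = 9.92e-26). E-boxes (CANNTG) were at 61.3% of summits and 53.8% of flanks (exact test, adjusted p = 0.0485), but at 58.6% of GC-matched windows (adjusted p = 0.44, in a range from 0.000537 to 1). The Meis site TGACAG was at 11.2% and 7.28% (exact test, adjusted p = 0.0633) and passed the threshold within 50 bp of summits (8.11% against 2.91%, adjusted p = 0.00094, in a range from 0.00094 to 1). The GATA site WGATAA was at 24.3% and 26.4% (exact test, adjusted p = 0.566), and the forkhead site TRTTKRY at 46.4% and 45.1% (adjusted p = 0.747). At the strongest peaks of replicate 1 alone, WGATAA was at 24.6% against 31.8% of flanks (exact test, adjusted p = 0.0294, in a range from 0.0294 to 1), and TRTTKRY at 46.9% against 47.3%. The control sequence TTAAKR was less frequent at summits (28.7% against 39.5%, exact test, adjusted p = 0.00157), a call lost with the strongest peaks of replicate 2 alone (0.516) and of replicate 1 alone (0.0555). Summit windows had a GC content of 41.7% and flanks 35.8%. Against GC-matched windows TTAAKR was higher at summits by its share, 28.7% against 22.9%, without passing the threshold (exact test, adjusted p = 0.0759, in a range from 0.00457 to 1).

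**Figure D3:**
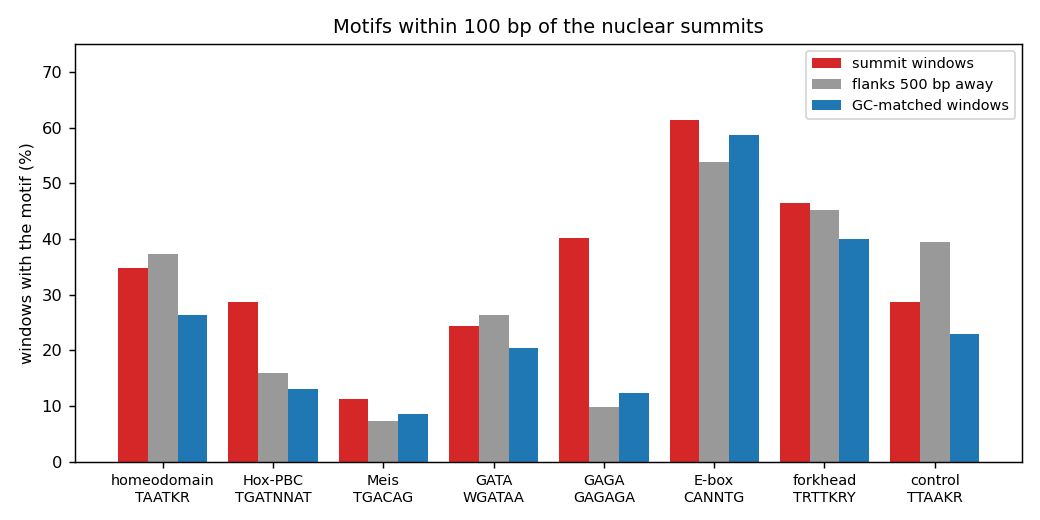
Share of windows with each of 8 motifs, in percent, within 100 bp of the 481 nuclear summits (red), in flanks centred 500 bp away (grey) and in random windows matched on GC content and on position inside or outside gene start windows (blue). GAGAGA stands at 40.1% of summits against 9.77% of flanks and 12.27% of matched windows, and TGATNNAT at 28.7% against 16% and 13.1%.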

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

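One signal lay outside the main analysis. On the mitochondrial genome of 13794 bp, the thresholded list held 21 peaks, 4.18% of all listed peaks. They covered 42.7% of that genome, had a median signal value of 133 against 42.7 for nuclear peaks, and made up 11 of the 15 strongest peaks, the strongest of all lying in ND5 (position 12399, signal value 408).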

How the results depend on the processing

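Of 47 results, 14 kept their direction and side of the threshold under every alternative run for them, among them the promoter share (51.6 to 78.6%), the ribosomal protein list (17.3 to 28.8%), the chemoreceptor list (0.291 to 0.874%), GAGAGA at summits (26.8 to 41.0%) and the Spearman correlation of the replicates (0.247 to 0.364). The results named here were the only ones of the 14 past the threshold. The others were gene lists that passed it in no setting. Where a value moved, the cause was not tested unless the alternative itself changes the set of peaks, windows or genes counted. Leaving out mitochondrial peaks, X or the mab-5 to egl-5 region, X alone and Ensembl gene names were chosen after seeing the data. Peaks recovered in the replicates rose to 81.6% with the strongest 1004 peaks of each and to 97.6% with all, and 204 listed peaks were left when both replicates had to cover them. The 50 kb margin put the density around mab-5 at percentile 99.90. Targets numbered 220 among the 251 strongest listed peaks and 783 with the 5000 bp window, against 496. Among these 251, the mab-5-linked list passed the threshold (15.4%, exact test, adjusted p = 0.0315), and the central share of 56.4% missed it. Cell death genes (0%) turned below the overall share of that setting, and collagen genes (1.28%) turned above it. With the narrow window, germline genes (2.13%) turned above the overall share. With the 5000 bp window, Hox (33.3%) and heat shock genes (12.12%) lost their calls, nuclear hormone receptors (0.372%) and C-type lectins (0.837%) passed below, and guidance (6.82%) and Notch genes (4.35%) turned above. With the nearest start alone, guidance (6.82%) and muscle genes (8.82%) turned above and heat shock genes (6.06%) lost the call. Rotated flags ended the Hox (33.3%) and heat shock (12.12%) calls, and leaving out the mab-5 to egl-5 region ended the Hox call (16.7%). With 1 replicate's own strongest peaks in place of the thresholded list, values ran from 16.7 to 18.6% on X, 4 to 7 lists called, 9.68 to 16.13% for Wnt, 5.56 to 13.9% for cell cycle, 7.69 to 12.8% for translation factor, 0 to 5% for M lineage, 0 to 5% for epidermal regulator, 2.94 to 8.82% for muscle, 0 to 3.57% for pan-neuronal and 2.13 to 6.38% for germline genes. The Wnt, cell cycle and translation factor calls were lost with replicate 1 alone. Over the same 2 settings TAATKR ran from 32.2 to 37.1%, TTAAKR from 32.2 to 32.3%, WGATAA from 24.4 to 24.6% and TRTTKRY from 46.5 to 46.9%. TTAAKR lost its call in both, TAATKR turned above its flanks with replicate 2 alone, and with replicate 1 alone TRTTKRY turned below and WGATAA passed the threshold. For the thresholded peaks with 1 replicate's own signal values, the median of promoter minus distal peaks ran from -1.89 (replicate 1, past the threshold) to -0.328. Within 50 bp of summits, TAATKR (19.1%) turned above its flanks, TRTTKRY (25.6%) turned below and TGACAG (8.11%) passed the threshold. Against flanks 1000 bp away, TAATKR (34.7%) turned, TGACAG (11.2%) passed and CANNTG (61.3%) and TTAAKR (28.7%) missed it. Against GC-matched windows, TAATKR (34.7%), WGATAA (24.3%) and TTAAKR (28.7%) turned above and CANNTG (61.3%) lost its call. Without X, TGACAG (11.6%) passed. On X alone only 1 motif was called, GAGAGA, while TGATNNAT (27.6%), TGACAG (9.21%), CANNTG (63.2%) and TRTTKRY (56.6%) turned below their flanks and TTAAKR (26.3%) lost its call. Density around mab-5 was not run on the ce10 lists, whose gene coordinates were not used here. No paired analysis was possible because the design has 1 group. Read depth, which is unknown, limits what the absence of a peak can show.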

Other observations

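In this part, GCGCAGGG and its comparisons between chromosomes, with matched windows and by peak strength were chosen after the strongest X peaks had been seen, and the 5 housekeeping classes and the comparison of gene start shares between X and the autosomes after the results they follow; the splits of the Hox-PBC composite were chosen after its share over all summits and before their own results. Genes of the Wnt pathway also had listed peaks outside gene start windows. cam-1, a ROR-type receptor gene, held 3 listed summits in its introns (II, 9299897, 9308664 and 9307100, with signal values of 75.1, 46.6 and 44.1), and mom-1 held 1 more (X, 6296622, signal value 69.9), which is among the 10 X summits with GCGCAGGG. unc-62 had 3 summits from 10000 bp upstream to its end, at 4491931, 4502924 and 4507959 on V. These genes were singled out after their values were seen.

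Peaks at ribosomal protein genes may be part of a wider presence at the starts of broadly expressed genes. Of 165 genes in 5 other classes (proteasome, cytosolic chaperonin, mitochondrial ribosomal protein, tRNA synthetase and V-ATPase), 12 were targets, or 7.27% (exact 95% interval 3.81 to 12.4%, Fisher's exact p = 0.00088). They included rpn-3, rpt-2, pbs-5, cct-1 and vha-8, of which rpn-3 and cct-1 shared their summits with hsp-110 and mig-5. No single class passed after adjustment (adjusted p from 0.12 to 0.395), and the combined share lay below the 28% of ribosomal protein genes, so the hypothesis leaves the height of that share open.

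GAGA repeats stood at 40.1% of summits and 9.77% of flanks. GC content is argued against as the whole source, since GC-matched windows carried GAGAGA in 12.27% of cases (exact McNemar p = 2.45e-21). Other aspects of base composition were not matched and stay open. A feature of gene starts in general is argued against too, since 48.9% of the 176 summits outside start windows carried it against 11.9% of their flanks (exact McNemar p = 9.04e-13). Sites that any immunoprecipitation recovers from open chromatin stay open and untested, because lists for other factors and the control are not analysed here. With 1 group, no biological explanation was tested.

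The density of peaks around mab-5 and egl-5 may come from the fusion protein, or from extra copies of the inserted region. In the 4 windows of 5 kb between the 2 genes that hold no listed peak, the median percentile of relaxed peaks was 67.5 in replicate 2 and 77.0 in replicate 1, while in the pooled list the 4 percentiles were 94.3, 14.99, 14.99 and 66.9. Extra copies had been taken to need values above 90 in both replicates, and their absence values below 75 in both, so this test decides nothing. It also used no window left of mab-5, where pooled relaxed summits ran over the neighbouring genes from 7757046 to 7776580. To the right, the pooled list had no summit between 7795659 and 7808479, while each replicate's list held some there. The pooled density around mab-5 thus did not run unbroken to egl-5. Around unc-119 the percentiles were 98.3 and 59.7 in replicates 1 and 2, and 98.2 and 94.5 with 50 kb on each side (pooled list 92.8 and 99.43). With 20 kb on each side, the replicates met neither limit set in advance for extra copies of unc-119, so that test decides nothing either. The gene lies elsewhere on chromosome III, and whether its copies go with those of mab-5 is not given in the sources used here. Extra copies of the mab-5 region stay open, as the extent and copy number of the insertion are not given in the sources used here, and no biological explanation was tested.

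GCGCAGGG, the core of the motif at recruitment sites of the X-specific dosage compensation complex, lay within 100 bp of 10 of 76 X summits (13.2%) and 1 of 405 autosomal summits (0.247%). Of the 10 strongest X summits 7 carried it, among them the site upstream of xol-1, against 3 of the other 66, which restates what led to the choice of the motif. Of 76 GC-matched X windows, 0 held it (0%, which allows a share of up to 3.95%). X holds only 4.57 such sites per Mb, so a count of 0 was likely in any case. Because the motif was also chosen from these peaks, this comparison cannot decide on base composition or the abundance of the motif, and no p is given. TGATNNAT was carried by 2 of the 10 X summits with GCGCAGGG and by 19 of the other 66 (Fisher's exact p = 0.717). The summits with GCGCAGGG but without TGATNNAT argue against Hox-PBC composites as their source, as far as this sequence stands for the composite. Whether the overlap of the 2 sequences is larger or smaller than at the other X summits was not decided. Apart from that overlap no biological explanation was tested, and recovery of these sites by any immunoprecipitation may also account for the 13.2%, since no other list was analysed here.

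TGATNNAT was more frequent at the 176 summits away from gene starts than at the 305 in start windows (40.3% against 22%, odds ratio 2.40, Fisher's exact p = 2.6e-05). Against their own flanks, only those away from gene starts passed (17.05% of flanks, adjusted p = 1.22e-05, against 14.4% and 0.066 inside, exact McNemar tests). As a hypothesis, distal elements may hold many of the Hox-PBC sites. The composite was not shown to avoid GAGA summits (26.9% with GAGAGA against 29.9% without, odds ratio 0.866, Fisher's exact p = 0.538). It was also not shown to favour the stronger peaks (30.4% against 27%, odds ratio 1.18, Fisher's exact p = 0.421).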
